A study of Mus musculus with 8 samples.

How the data were processed

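Total RNA was measured on 8 Affymetrix gene arrays, 4 from R1 mouse embryonic stem cells transfected with a pLKO.1 plasmid encoding a hairpin against GFP (shGFP) and 4 from cells transfected with a pLKO.1 plasmid encoding a hairpin against MKRN1 (shMKRN1). Per the labels' protocols, cells were seeded on gelatin in medium with LIF and 15% serum, received 2 µg of plasmid with a cationic lipid 48 h later, were selected with 2 µg/mL puromycin for 4 days and were lysed on day 6 after transfection. Samples were grouped by the hairpin named in their titles. The titles number the arrays 1, 3, 5 and 7 for shGFP and 2, 4, 6 and 8 for shMKRN1, and these numbers are used here as names. The labels do not say whether the 4 samples of a group came from separate transfections, so p-values measure the spread between these samples, which may be technical.

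The deposited table holds log2 expression values for 34760 probe sets, made with RMA per the submitters' processing notes; its version is not given in the sources used here. RMA subtracts a background, brings the arrays to a common distribution and summarises the probes of a probe set. A change in the amount of RNA per cell that affects most genes alike is therefore not visible, and changes of dim probe sets are understated. The array medians still differed slightly in the table (7.14 to 7.24), so 2 further scalings were tried. Values ranged from 1.95 to 14.5, and no 2 columns were identical. All columns belonged to the 8 samples.

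Gene names came from the platform annotation supplied with the table: 21640 probe sets had 1 gene symbol, 1321 had several and 11799 were not named. Probe sets with several symbols were not used for genes. Where 1 symbol had several probe sets (954 genes), the probe set with the highest mean over all 8 arrays was kept, which left 19937 genes. Of the 45 called genes with several probe sets, 37 had all their other probe sets changed in the same direction. Entrez numbers matched 19855 genes to the RefSeq gene table of GRCm38.p6, which was used for current names, synonyms and the order of neighbouring genes only.

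Differences between shMKRN1 and shGFP were fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit on the group, eBayes with default settings, 6 residual degrees of freedom and 4 prior degrees of freedom), with no filter on low values and no covariate. Tests were two-sided and p-values were adjusted over the 19937 genes by Benjamini-Hochberg, with a threshold of 0.05. Single values (Mkrn1 and the other makorin genes, and the mean score of a gene list) were also tested with an exact two-sided permutation test over the 70 assignments of 8 arrays to groups of 4 and 4, in which the smallest possible p is 0.0286. A list score is the mean, over the members of a list, of an array's log2 value minus the shGFP mean of that gene.

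Before the data were examined, 32 gene lists were fixed, covering 753 genes, of which 677 were measured. They comprised naive and general pluripotency, formative and primed epiblast, primitive endoderm, mesendoderm and early mesoderm, neural ectoderm, trophectoderm, 2-cell-like cells, germ line, fibroblasts, imprinted genes, p53 targets, apoptosis machinery, reported MKRN1 protein substrates, integrated stress response and amino acid genes, unfolded protein response of the endoplasmic reticulum, heat shock, oxidative stress, stress granule and cytoplasmic mRNA-binding proteins, interferon and double-stranded RNA response, microRNA pathway, DNA replication and G1/S, mitosis and G2/M, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, FGF/ERK response, LIF/STAT3 response, WNT response, TGF-beta/Nodal and BMP response, 26S proteasome, and lysosome and autophagy. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 32 lists. Camera with a correlation estimated from the data and fry were the alternatives. Camera compares a list with all other genes; fry tests whether the genes of a list move, on balance, in 1 direction.

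The named genes were also chosen by a rule fixed beforehand. It took the makorin genes, then the 12 largest increases and the 12 largest decreases among genes that passed the test, whose groups did not overlap and whose higher group lay above the median of all genes, then up to 4 members of each list with the smallest p. Predicted genes were passed over. Genes outside this rule are marked in the text as chosen after their values were seen.

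On simulated arrays with the spread of these data and 200 changed genes among 19937, the fit recovered 20.9% of genes changed 1.2-fold, 83.6% of those changed 1.5-fold and 98.5% of those changed 2-fold, and 3.57% of its calls were wrong. In that simulation a list raised 1.2-fold was called, and no other list passed camera. Genes were drawn there independently of each other, while the estimated correlation within lists of these data reached 0.5 (mitosis and G2/M). The simulated rates of wrong calls, of genes and of lists, therefore do not cover correlated genes. The number of arrays limits the precision: with 4 arrays per group most changes near 1.2-fold were missed in the simulation. Its 200 changed genes are fewer than the 896 genes called in these data. Its cut-off on the unadjusted p was therefore stricter, and the share recovered in these data may differ.

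Alternatives fixed before the data were examined were quantile normalization, centring on the array median, a filter at the median level, eBayes with a trend and with robust settings, array weights, a block of adjacent sample numbers, the mean of all probe sets of a gene, adjustment over all probe sets, a per-gene Welch test, treat against a 1.2-fold change, and leaving out each array. Leaving out arrays 7 and 8 together was added after seeing the data. A planned test of transcripts that match the hairpin seed in their 3′ UTR was not run, because no transcript sequences were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.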

Results

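Gene expression was measured in R1 cells, a male mouse embryonic stem cell line of 129X1 x 129S1 background, after transient knockdown of Mkrn1. MKRN1 is an E3 ubiquitin ligase that also binds mRNA, and the comparison asks which transcripts differ in a stem cell population that carries a hairpin against it. The control population carried a hairpin against GFP, a jellyfish gene absent from these cells. Each group had 4 arrays, and the cells were lysed on day 6 after transfection, at the end of 4 days of puromycin. Array medians lay between 7.14 and 7.24 on the log2 scale, and Pearson correlations between arrays across genes, which are not independent replicates, between 0.988 and 0.996. The leading principal component held 37.6% of the variance and set array shGFP 7 (23.2) apart from the other shGFP arrays (-3.45 to 6.2) and array shMKRN1 8 (7.46) apart from the other shMKRN1 arrays (-15.2 to -6.02). The next component, with 28% of the variance, placed the shGFP arrays between -1.78 and 15.6 and the shMKRN1 arrays between -14.8 and -3.09.

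Mkrn1 (Entrez gene 54484) was lower in all 4 shMKRN1 arrays than in any shGFP array. Its log2 level was 10.44 ± 0.069 in shGFP and 9.84 ± 0.036 in shMKRN1 (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). The change of -0.60 (SE 0.052; limma adjusted p = 0.000767) left 66.2% of the control level, with a 95% confidence interval of 61% to 71.7%. Mkrn1-ps1, a pseudogene copy of Mkrn1, fell by 0.53 (SE 0.084; limma adjusted p = 0.00854). Whether its probes share sequence with Mkrn1 was not tested, so the pair is not counted as independent. For the related ligase gene Mkrn2 the change was -0.01 (SE 0.052; limma adjusted p = 0.92), not past the threshold. The imprinted Mkrn3 lay at 5.91 in shGFP and 6.10 in shMKRN1 (limma adjusted p = 0.391), within the range of the silent olfactory and vomeronasal receptor genes, 95% of which lay below 6.53, so a change in it could not be assessed.

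**Figure D1:**
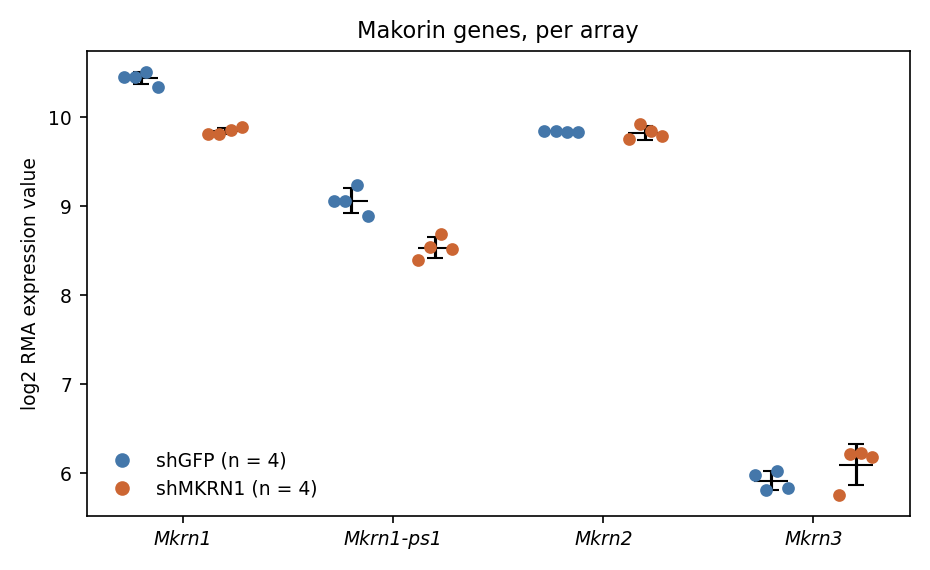
RMA log2 expression value of 4 makorin genes (y axis) in each array, shGFP in blue and shMKRN1 in orange; bars give the mean ± SD (n = 4). The groups are separate for Mkrn1 and Mkrn1-ps1 and overlap for Mkrn2 and Mkrn3, where array shMKRN1 2 lies at 5.76.

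Most transcripts that changed in the knockdown were higher. Of 19937 genes, 896 passed the limma test at an adjusted p of 0.05 (4.49%), 729 of them higher and 167 lower in shMKRN1. The changes were mostly small, with a median of 1.26-fold. In all, 106 genes changed at least 1.5-fold (81 higher, 25 lower) and 13 at least 2-fold (12 higher, 1 lower, Lce1h). The count past 1.5-fold was much lower with only genes above the median level and by treat, as given in the part on processing. The groups did not overlap for 889 of the 896 genes, and for 14.1% of all genes against 2.86% by chance. The median change of all genes was 0.01. Quantile normalization gave 806 higher and 290 lower genes, and median centring 875 higher and 125 lower. The count of 896 depended on single arrays: it was 505 without shGFP 1, 324 without shGFP 3, 353 without shMKRN1 2, 387 without shMKRN1 4 and 309 without shMKRN1 6. Under other limma settings it lay between 378 (adjusted over every probe set) and 2757 (array weights).

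**Figure D2:**
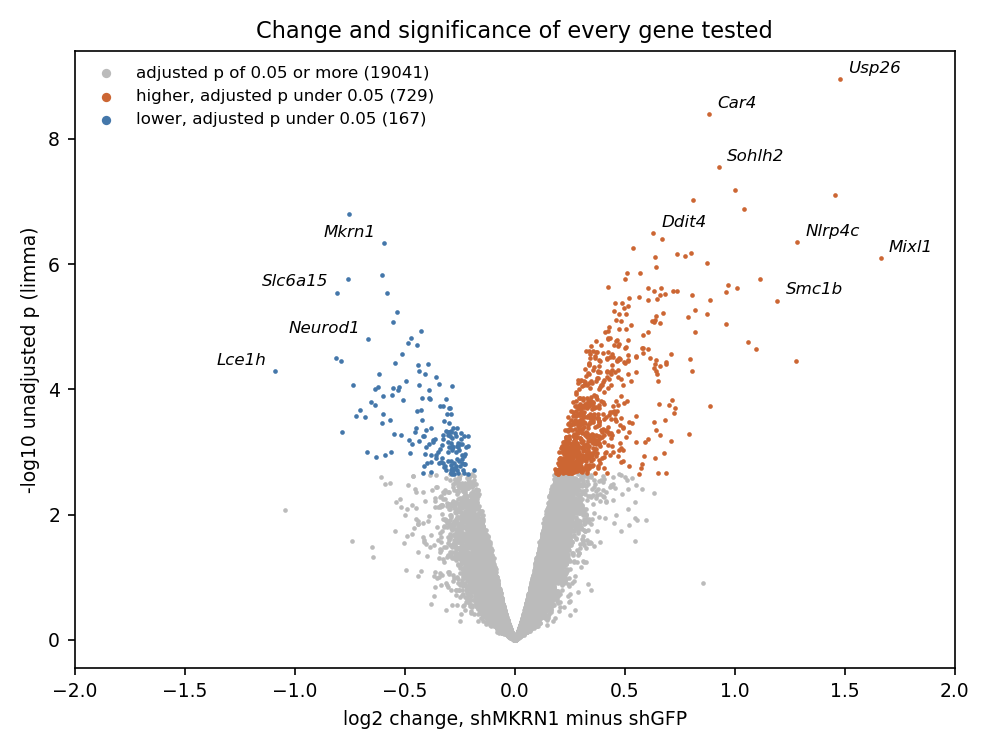
Log2 change, shMKRN1 minus shGFP (x axis), against -log10 of the unadjusted limma p (y axis) for 19937 genes, 1 point per gene. Orange points are the 729 genes that were higher and blue points the 167 that were lower at an adjusted p under 0.05; Mkrn1 is labelled among the lower genes.

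Mixl1, a homeobox factor of the primitive streak, led the 12 increases taken by the naming rule. It rose 3.17-fold, from a log2 level of 7.50 ± 0.30 to 9.16 ± 0.24 (SD, n = 4 each; limma adjusted p = 0.000882). Eomes, a T-box factor of the streak and the trophoblast, rose 1.95-fold (log2 change 0.96, SE 0.12; adjusted p = 0.00268), and the signalling ligand gene Wnt8a also 1.95-fold (0.96, SE 0.10; adjusted p = 0.00154). Usp26, a deubiquitinase gene expressed in testis, rose 2.78-fold and had the smallest p of all genes (1.48, SE 0.069; adjusted p = 2.19e-05). The meiotic cohesin gene Smc1b rose from 6.45 in shGFP, which is within the range of the silent receptor genes, to 7.64 in shMKRN1. The increases also included the germ cell ADP/ATP carrier gene Slc25a31 (1.06), the germ cell transcription factor gene Sohlh2 (0.93) and the meiotic chromosome axis gene Hormad1 (0.89). The other 4 increases were in the calmodulin-like Calml4 (1.04), the lipoxygenase gene Alox15 (1.01), the carbonic anhydrase gene Car4 (0.88) and the acyltransferase gene Mogat2 (0.88). All 12 had adjusted p-values between 2.19e-05 and 0.00409. Of the 13 genes past 2-fold, 6 fall outside this naming rule, 5 for a low level and 1 as a predicted gene. Of those 5, Nlrp4c and Ccdc152, chosen after their values were seen, lay within the range of the silent receptor genes in both groups (4.91 and 4.16 in shGFP, 6.19 and 5.26 in shMKRN1), so a 2-fold change cannot be assigned to them.

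The decreases were smaller and fewer. Lce1h, a late cornified envelope gene of the epidermis, fell by 1.09 on the log2 scale (SE 0.16; limma adjusted p = 0.00635), and Crct1, a gene of the same epidermal gene cluster, fell by 0.70. The sialyltransferase gene St6gal2 and the neutral amino acid transporter gene Slc6a15 each fell by 0.81. Igfbp7, which binds insulin-like growth factors, fell by 0.78, the cytochrome P450 gene Cyp2b23 by 0.76, the neuronal calcium-binding Necab1 by 0.73 and Inhba, which encodes an activin subunit, by 0.72. Timp3, an inhibitor of metalloproteinases, and the neuronal transcription factor gene Neurod1 each fell by 0.67, the protease inhibitor gene Spink1 by 0.65 and Uprt by 0.63. Adjusted p-values of the 12 lay between 0.00134 and 0.0318. All 12 increases and 7 of the 12 decreases kept their call without each array in turn. At the least favourable array the adjusted p was 0.0544 for Crct1 (without shMKRN1 6) and 0.0511 for Uprt (without shGFP 3). Inhba lost its call without shGFP 3 or shMKRN1 6 (up to 0.0607), Igfbp7 without shGFP 3 or shMKRN1 2, 4 or 6 (up to 0.0772) and Timp3 without shGFP 3 or shMKRN1 4, 6 or 8 (up to 0.102).

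**Figure D3:**
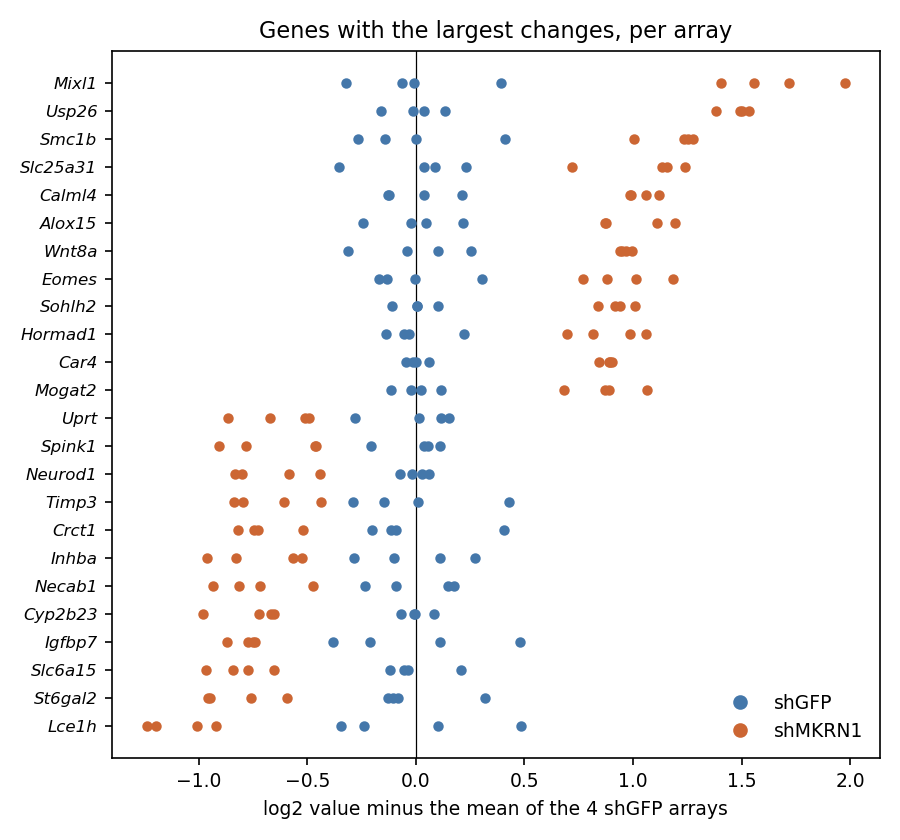
Log2 value minus the mean of the 4 shGFP arrays (x axis) for the 12 named increases and 12 named decreases (y axis), 1 point per array, shGFP in blue and shMKRN1 in orange. The groups do not overlap for any of the 24 genes; Mixl1 lies farthest to the right and Lce1h farthest to the left.

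Of the 32 gene lists, 13 passed camera at the preset correlation, 11 higher and 2 lower in shMKRN1. With an estimated correlation, 1 list passed, the integrated stress response and amino acid genes. With fry, 7 did. The count of lists did not stand out from other groupings: 6 of the 35 splits of the 8 arrays into 4 and 4, the real one included, gave at least 13 lists, and the highest other gave 15. For 8 lists the scores of the groups did not overlap (exact permutation p = 0.0286, adjusted over the 32 lists 0.114).

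**Figure D4:**
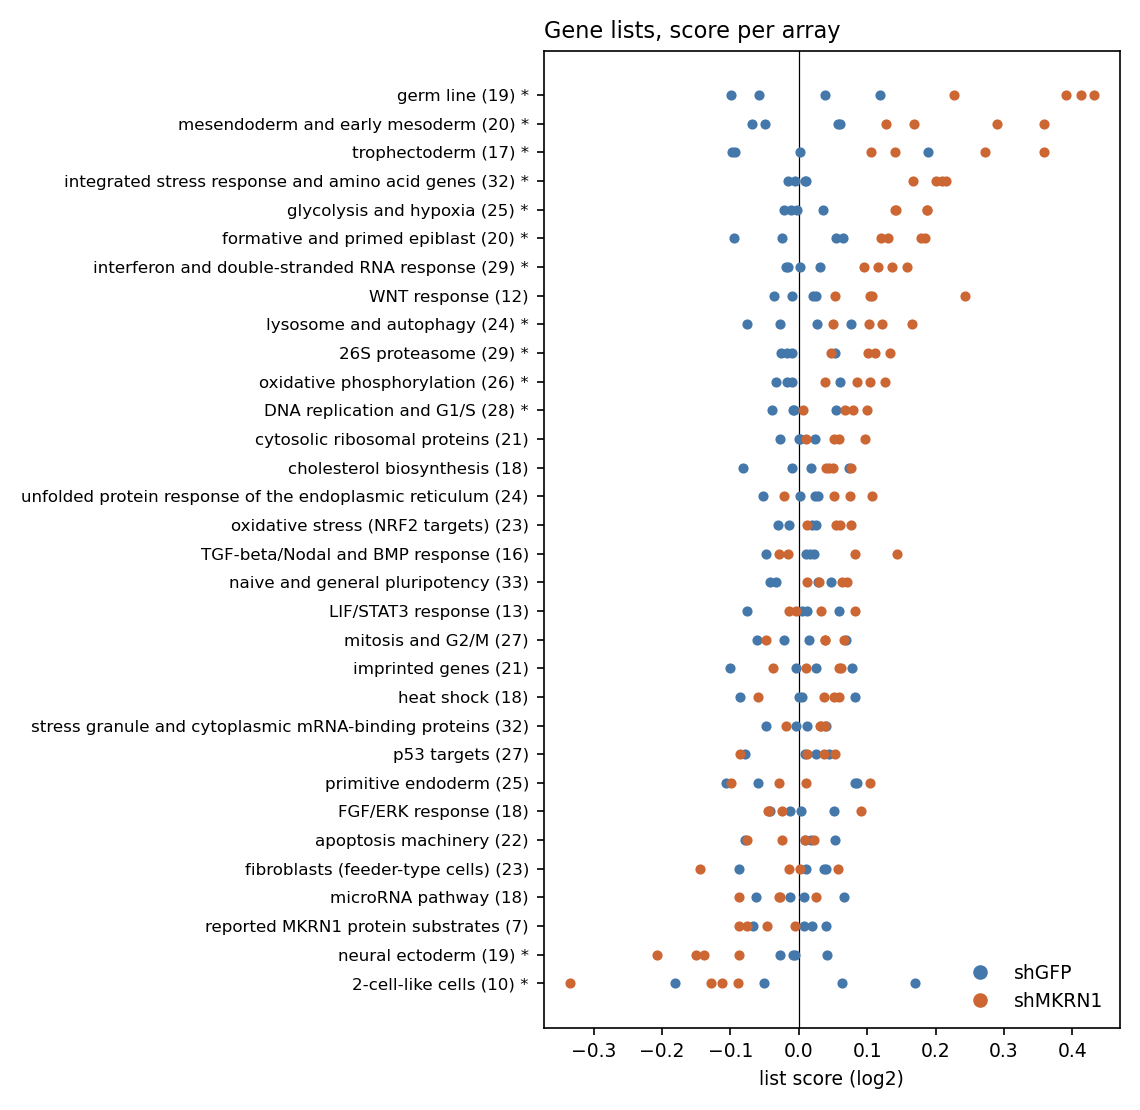
List score per array (x axis), the mean over the measured members of the log2 value minus the shGFP mean of each gene, for 32 gene lists (y axis, measured members in brackets), shGFP in blue and shMKRN1 in orange. Asterisks mark the 13 lists past camera at the preset correlation; the germ line list has the highest shMKRN1 mean (0.37) and the 2-cell-like list the lowest (-0.17).

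Genes of the germ line were higher in shMKRN1. Of 19 measured members of that list, 7 rose and none fell (12 and 0 adjusted over the list alone). The median change was 0.28, and camera gave an adjusted p of 4.65e-06. With only genes above the median level the median was 0.595 and the camera adjusted p 0.00604. With an estimated correlation the adjusted p was 0.215. Besides Hormad1 and Slc25a31, the members with the smallest p were the germ cell RNA-binding protein gene Dazl (0.80, SE 0.11; adjusted p = 0.00513) and Mael (0.64, SE 0.090; adjusted p = 0.00517), a factor of transposon silencing in germ cells. All 4 kept their calls without each array in turn. Transcripts of 2-cell-like cells did not move with them: none of 10 measured members passed limma (4 had an unadjusted p under 0.05, all lower). That list was lower by camera (median -0.16, adjusted p = 0.00732; 0.634 with an estimated correlation). Its call was lost without shGFP 1 (median -0.07, adjusted p = 0.064) and without shMKRN1 8 (median -0.11, adjusted p = 0.0674), and its median was -0.28 without shGFP 7.

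Mesendoderm, formative and trophectoderm genes were higher and neural ectoderm genes lower by camera, and differences between these lists were not tested. Of 20 mesendoderm and early mesoderm genes, 4 rose and none fell (5 and 0 adjusted over the list alone, Wnt3 being the fifth): Mixl1, Eomes, Lhx1 (from 6.40 in shGFP, within the range of 95% of the silent receptor genes, to 7.01 in shMKRN1) and Fgf8 (0.46, SE 0.086). Camera gave an adjusted p of 0.00594, and 0.634 with an estimated correlation. The mean change of 0.24 exceeded the median of 0.09. Of 20 formative and primed epiblast genes, 4 rose and none fell (9 higher and 1 lower, Grhl2 at -0.15, adjusted over the list alone): Wnt8a, Car14 (0.51), Zic5 (0.43) and the de novo DNA methyltransferase gene Dnmt3a (0.25, SE 0.048). That list had an adjusted p of 0.0058, and 0.634 with an estimated correlation. Of 17 trophectoderm genes, 3 rose (6 adjusted over the list alone): Eomes, which also counts as mesendoderm, Tfap2c (0.44) and Fgfr2 (0.36). Camera gave an adjusted p of 0.00414, and 0.634 with an estimated correlation. Neural ectoderm genes were lower, with 1 of 19 members, Neurod1, past the threshold and 4 adjusted over the list alone (median -0.15; adjusted p = 0.000137, and 0.163 with an estimated correlation). The other 3 of those 4 were Fabp7 at -0.46, Gbx2 at -0.22 and Pax6 at -0.19. With genes below the median level left out, the calls of the mesendoderm (adjusted p = 0.402), formative (0.249) and trophectoderm (0.0767) lists were lost. Without 1 array the medians of these 4 lists moved over 1.5 times. The mesendoderm median went from 0.09 to 0.13 without shGFP 3, 0.15 without shGFP 7 and 0.14 without shMKRN1 4. The formative median went from 0.13 to 0.08 without shGFP 1, the trophectoderm median from 0.21 to 0.13 without shMKRN1 2 and the neural median from -0.15 to -0.09 without shMKRN1 6. The mesendoderm call was also lost with array weights (0.1), and the formative call with quantile normalization (0.0707).

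The pluripotency list as a whole did not pass (camera adjusted p = 0.911). Of 33 measured members, 4 rose and 1 fell (5 and 2 adjusted over the list alone, with Tbx3 at 0.37 and Nr0b1 at -0.20 besides). Dppa3, a gene of naive stem cells and the early germ line that the germ line list also holds, rose by 0.79 (SE 0.16; limma adjusted p = 0.0233). Nanog rose by 0.25 (SE 0.050; adjusted p = 0.0256), Fbxo15 by 0.40 and Klf2, chosen after its value was seen, by 0.32. The DNA demethylase gene Tet1 fell by 0.23 (SE 0.046; adjusted p = 0.0238). The median of the list was -0.01, its mean 0.04, and camera's direction lower. Of 25 primitive endoderm genes, Fst rose (0.50, SE 0.10) and no other passed, also adjusted over the list alone (list adjusted p = 0.703; median 0.02, mean -0.003, camera's direction lower). Of 23 markers of fibroblasts, the other cell type such cultures can hold, 2 rose, Pdgfrb (0.35) and Col1a1 (0.37), and 2 fell, Timp3 and the matrix glycoprotein gene Thbs1, which fell by 0.63. Adjusted over the list alone Cd44 (0.47) and S100a4 also passed, which made 3 higher and 3 lower. S100a4 lay within the range of the silent receptor genes (5.63 in shGFP, 5.37 in shMKRN1) and is not read as expression. The list did not pass (adjusted p = 0.813; median 0.03, mean -0.02, camera's direction lower). Of 21 imprinted genes, Sgce rose (0.48, SE 0.10), also adjusted over the list alone, and the list did not pass (adjusted p = 0.804). Of the called genes named for these lineage lists, Mixl1, Eomes, Lhx1, Wnt8a, Car14, Zic5 and Neurod1 kept their calls without each array in turn. Grhl2, Tbx3, Nr0b1, Cd44 and S100a4 were chosen after their values were seen. The other called genes lost their calls without at least 1 array, most often shGFP 3 and shMKRN1 2, 4 or 6, at adjusted p-values of up to 0.131. Klf2, Pdgfrb and Col1a1 each kept their call in only 1 of the 8 fits.

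Amino acid and integrated stress response genes were higher as a list. Of 32 measured members, 11 rose and none fell (17 and 0 adjusted over the list alone), and 30 of 32 had a higher mean in shMKRN1. The median change was 0.19, and camera gave an adjusted p of 1.91e-10, or 0.027 with an estimated correlation. Ddit4, a stress-induced inhibitor of mTORC1, rose 1.55-fold (0.63, SE 0.053; limma adjusted p = 0.000711), and Chac1, a glutathione-degrading enzyme gene, also 1.55-fold (0.63, SE 0.067; adjusted p = 0.00154). The cysteinyl-tRNA synthetase gene Cars rose by 0.43 and Psat1, an enzyme of serine synthesis, by 0.36. All 4 kept their calls without each array in turn. The unfolded protein response of the endoplasmic reticulum did not pass as a list (adjusted p = 0.247), with 3 of 24 members higher, the same number adjusted over the list alone: Dnajb11 (0.33), Herpud1 (0.26) and Creld2 (0.23). In the heat shock list Bag3 (0.26) was past the threshold out of 18 members, also adjusted over the list alone (list adjusted p = 0.911). In the oxidative stress list Ephx1 rose by 0.47 and Gstm1 fell by 0.32 among 23 members (list adjusted p = 0.512). Adjusted over the list alone 2 rose, with Nqo1 at 0.27, and 1 fell. Each of the calls of Dnajb11, Herpud1, Creld2, Bag3, Ephx1 and Gstm1 was lost without at least 1 array, at adjusted p-values of up to 0.136. Bag3 lost its call whichever array was left out, and Creld2 kept its call in 1 of the 8 fits.

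Interferon and double-stranded RNA response genes were also higher, with 3 of 29 members past the threshold and none lower (11 and 0 adjusted over the list alone). These were Stat2 (0.30, SE 0.051), Usp18 (0.44, SE 0.079) and Ifi35 (0.43, SE 0.078). The list had a median change of 0.12 and a camera adjusted p of 0.0152, or 0.163 with an estimated correlation, and its call was lost with genes below the median level left out (0.287). The calls of the 3 genes were lost without shGFP 3 or without 1 or more of shMKRN1 2, 4 and 6, at adjusted p-values of up to 0.0565.

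Of 25 glycolysis and hypoxia genes, 5 rose and none fell (9 and 0 adjusted over the list alone). The list had a camera adjusted p of 4.65e-06, or 0.163 with an estimated correlation. The glucose transporter gene Slc2a3 rose 1.42-fold (0.50, SE 0.051; limma adjusted p = 0.00134), Vegfa by 0.43 (SE 0.055), the phosphofructokinase gene Pfkp by 0.42 (SE 0.064), the oxygen sensor gene Egln1 by 0.29 (SE 0.045) and P4ha1, chosen after its value was seen, by 0.30. Those that rose include few enzymes of glycolysis itself: Slc2a3 carries glucose, and Vegfa, Egln1 and P4ha1 are known hypoxia targets. The list's median of 0.15 was 0.10 without shMKRN1 8. The calls of Slc2a3, Vegfa, Pfkp and Egln1 held without each array in turn, and that of P4ha1 was lost without 4 of them (adjusted p up to 0.0598). Oxidative phosphorylation genes were higher by camera (median 0.08; adjusted p = 0.0054, and 0.634 with an estimated correlation), with Cox4i1 (0.25, SE 0.058) alone past the threshold among 26, also adjusted over the list alone. Proteasome subunits were higher (median 0.11; adjusted p = 0.000556, and 0.634 with an estimated correlation), with Psmd3 (0.27) and Psmc3 (0.23) past the threshold among 29 and 11 adjusted over the list alone. Of 24 lysosome and autophagy genes, 5 rose and none fell (8 and 0 adjusted over the list alone): Hexa (0.36), Ctsz (0.32), Ctsl (0.26), Npc2 (0.19) and Becn1 (0.19), the last chosen after its value was seen. That list had an adjusted p of 0.00134, and 0.634 with an estimated correlation. With genes below the median level left out, the calls of the oxidative phosphorylation (0.118) and lysosome (0.0767) lists were lost. The oxidative phosphorylation median was 0.05 without shGFP 7. The genes named here from the oxidative phosphorylation, proteasome and lysosome lists each lost their call without at least 1 array, at adjusted p-values of up to 0.153. Npc2 and Becn1 lost theirs whichever array was left out, and Psmc3 kept its call in 1 of the 8 fits. None of 18 cholesterol biosynthesis genes passed with limma (5 had an unadjusted p under 0.05), and the list had an adjusted p of 0.246. None of 21 cytosolic ribosomal protein genes passed either (7 had an unadjusted p under 0.05), and that list had an adjusted p of 0.21. No member of these 2 lists passed when adjusted over the list alone. The call of the cholesterol list appeared without shGFP 5 (0.0418) and that of the ribosomal list with array weights (0.045).

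Lists tied to what is known of MKRN1 held 1 called gene, Cnot6 of the microRNA pathway. Of 12 listed genes for reported MKRN1 protein substrates 7 were measured. None of these passed limma (1 had an unadjusted p under 0.05), and the list had a median of -0.05 (camera adjusted p = 0.175). The arrays measure RNA and do not show whether the levels of these proteins changed. For Fadd the change was -0.11 (SE 0.048; limma adjusted p = 0.232). None of 32 stress granule and cytoplasmic mRNA-binding protein genes passed limma (3 had an unadjusted p under 0.05, and the list an adjusted p of 0.854). Larp4 was at 0.21 (SE 0.065; adjusted p = 0.0986). None of 27 p53 targets passed (5 had an unadjusted p under 0.05, and the list an adjusted p of 0.694), with Ddb2 at 0.31 (SE 0.084; adjusted p = 0.0699). None of 22 genes of the apoptosis machinery passed (6 had an unadjusted p under 0.05, and the list an adjusted p of 0.411), with Birc5 at 0.18 (SE 0.056; adjusted p = 0.102). No member of these 4 lists passed when adjusted over the list alone. The p53 targets had a median of -0.01 and a mean of 0.004, and camera's direction was lower. In the microRNA pathway list the deadenylase gene Cnot6 fell by 0.28 (SE 0.058; adjusted p = 0.025), the 1 member of 18 past the threshold, also adjusted over the list alone (list adjusted p = 0.199). Its call was lost without any 1 of 6 arrays (shGFP 1, 3 or 5, shMKRN1 2, 4 or 6; adjusted p up to 0.0825). The call of the substrate list appeared in quantile-normalized data (0.0437), with genes below the median level left out (0.0393) and without shGFP 7 (0.0396). That of the microRNA list appeared in quantile-normalized data (0.0216) and without shGFP 7 (0.0309).

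Cell cycle genes moved little. None of 28 DNA replication and G1/S genes passed limma (9 had an unadjusted p under 0.05), although the list was slightly higher by camera (median 0.07; adjusted p = 0.0458, and 0.796 with an estimated correlation). That call was lost without any 1 of 5 arrays (shGFP 1, 3 or 7, shMKRN1 4 or 6; adjusted p up to 0.216), with quantile normalization (0.123), with a block of adjacent sample numbers (0.0582) and with genes below the median level left out (0.359). None of 27 mitosis and G2/M genes passed (3 had an unadjusted p under 0.05, and the list an adjusted p of 0.911). No member of either list passed when adjusted over the list alone.

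Targets of the signalling pathways that govern these cells changed in both directions. In the LIF/STAT3 list of 13, the kinase gene Pim1 (0.51, SE 0.050; limma adjusted p = 0.00126) and Icam1 (0.40, SE 0.055; adjusted p = 0.00492) rose, and the receptor gene Lifr fell by 0.34 (SE 0.073; adjusted p = 0.0303). Adjusted over the list alone 2 rose and 2 fell, with Gbx2 as the other lower gene (list adjusted p = 0.924; median -0.02, mean 0.02, camera's direction lower). Of 18 FGF/ERK response genes, Myc fell by 0.29 (SE 0.057; adjusted p = 0.0221), and 3 rose and 3 fell adjusted over the list alone, with Spred1 (0.32), Dusp4 (0.26) and Dusp1 (0.19) higher and Fosl1 (-0.26) and Spry4 (-0.22) lower. The list did not pass (adjusted p = 0.804; median 0.03, mean -0.01, camera's direction lower). Of 12 WNT response genes, Sp5 rose by 0.49 (SE 0.095; adjusted p = 0.0207), and 4 rose adjusted over the list alone, with Wnt3 at 0.39, Lef1 at 0.22 and Nkd1 at 0.21. The list missed the threshold (adjusted p = 0.0589) and passed it in 5 other fits, between 0.0263 without shMKRN1 6 and 0.0491 without shGFP 3. Of 16 TGF-beta/Nodal and BMP response genes, Lefty2 (0.33) and Smad6 (0.31) rose, and 3 rose and 2 fell adjusted over the list alone, with Id3 at 0.23, Id2 at -0.36 and Ccn2 at -0.28 (list adjusted p = 0.748). Pim1 and Icam1 kept their calls without each array in turn. Dusp1, Dusp4 and Ccn2 were chosen after their values were seen. Lifr, Myc, Sp5, Lefty2 and Smad6 lost their calls without at least 1 array, at adjusted p-values of up to 0.128. Lifr and Smad6 each kept their call in only 1 of the 8 fits.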

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

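Leaving out arrays 7 and 8, and the tests on the scaling of the arrays, on 2-cell-like genes, on stress of the endoplasmic reticulum and on double-stranded RNA, were chosen after the results they examine were seen. Single arrays far from the other 3 of their group appeared in 18 of 426 groups of 4 (181 genes and 32 lists, both hairpins), where chance gives about 1 in 20, or 21.3. Array shMKRN1 2 stood apart for Mkrn3 (log2 level 5.76, against 6.19 to 6.22 in the others, all within the range of silent receptor genes), Bid (9.73, against 9.67 to 9.68) and the FGF/ERK list score (0.0905, against -0.0445 to -0.0251). Array shMKRN1 6 was low for Rplp1 (13.46, against 13.48) and S100a4 (5.21, against 5.41 to 5.43, within the same range). Array shMKRN1 8 was low for Smc1b (7.46, against 7.68 to 7.73), Nat8f2 (6.73, against 7.01 to 7.06) and Dgat2 (9.17, against 9.35 to 9.37). The same array was low in the scores of 2-cell-like cells (-0.335, against -0.128 to -0.0885) and of stress granule proteins (-0.0191, against 0.0309 to 0.0387). Array shGFP 1 was low for Cited1 (8.17, against 8.38 to 8.41), and array shGFP 5 high for St6gal2 (9.56, against 9.12 to 9.16) and Gbp3 (7.19, against 6.84 to 6.85). Array shGFP 7 was high for Zic5 (10.95, against 10.78 to 10.79). It was low for Fgfr2 (8.84, against 8.997 to 9.026), Ctsl (10.79, against 10.96 to 10.99), Hormad2 (6.56, against 6.81 to 6.85) and the TGF-beta list score (-0.0477, against 0.0103 to 0.0215).

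Probe sets without a gene name carried a signal that the comparisons of genes do not use. Of 11799 such probe sets, 98 passed the limma test adjusted over every probe set, 42 higher and 56 lower in shMKRN1. Over all 34760 probe sets 521 passed the same test, so those without a name were called less often. More of the 98 were lower than higher, the reverse of the called genes.

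More genes were higher than lower in shMKRN1 (729 against 167). At the adjusted threshold the real split stood alone in the number of called genes, which says nothing of their direction. Of the 35 splits of the 8 arrays, 1, the real one, called as many as 896, and the highest other split called 0. This share is the smallest that 35 splits can give, and each other split mixes the hairpins, so real differences widen its error. Chance is therefore not excluded. At an unadjusted p under 0.05, 2 of the 35 splits gave as many genes (3888 in the real one, 3907 in the highest other). The count past 1.5-fold (106, 1 of 35 splits, highest other 0) adds nothing because those genes must first be called. A shift between arrays left by the normalization and a rise of dim probe sets are argued against as the whole account. After quantile normalization or median centring at least 73.5% of called genes were higher, against 81.4% as deposited. The 1194 olfactory and vomeronasal receptor genes, silent in these cells, had a median change of -0.035 (95% interval over genes, not arrays, -0.042 to -0.028). It was below 0 under both scalings too. The median change was 0.041 among genes above the median level and 0.0077 over all genes. A difference between arrays that varies with level is therefore not excluded.

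Germ line genes were higher in shMKRN1 (median 0.28), although 3 of the 35 splits gave this list a camera p as small, so that chance is not excluded for the list. A shift of dim probe sets is argued against, since the median lay at percentile 100 of 10000 random lists matched on level (their highest was 0.16), and so are arrays 7 and 8, without which the median was 0.30. The rise that more cells in the 2-cell-like state would give was not seen. Of the 10 measured among 18 listed 2-cell-like genes, 1 had a higher mean in shMKRN1. The scores of that list overlapped between the groups (exact permutation p = 0.171), and 10 of the 35 splits gave it a camera p as small. Its direction is thus not settled, and this explanation is not excluded. The germ line score rose above the 2-cell-like score by 0.53 (exact permutation p = 0.0286, the smallest possible), in 16 of 16 pairs of arrays. That difference follows from list results already seen and adds no separate support. A seed match of the hairpin to other transcripts cannot be told apart from the loss of MKRN1, because 1 hairpin against Mkrn1 was used. A response to lower MKRN1, the difference named by the design, may account for the change and was not tested separately.

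Integrated stress response genes were higher in shMKRN1 (median 0.19), and 1 of the 35 splits, the real one, gave this list a camera p as small. The unadjusted camera p was 5.98e-12, against 1.55e-09 in the closest other split. Splits that mix the hairpins thus also gave this list very small camera p-values. A shift of abundant genes is argued against, with the median at percentile 100 of 10000 random lists matched on level (their highest was 0.12). The integrated stress response score rose above that of the unfolded protein response by 0.14 and above that of the interferon list by 0.07. For each, the exact permutation p was 0.0286, the smallest possible, in 16 of 16 pairs of arrays. Equal rises of these lists are thus not what the arrays show. The lists had been seen before, and neither stress of the endoplasmic reticulum nor a double-stranded RNA response need raise them equally. The differences therefore do not argue against either. Both groups received 2 µg of a hairpin plasmid, so a response to it that they share would not show. A double-stranded RNA response that differs with the hairpin's sequence or uptake and raises the 2 lists unequally cannot be told apart from an effect of lower MKRN1, because the interferon list was higher too (median 0.12).

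The number of gene lists past the threshold does not stand out from other groupings. In 6 of the 35 splits, the real one included, at least 13 lists passed camera, and the highest other split gave 15. All 5 of those other splits keep arrays 7 and 8 in 1 group, as do 15 of the 34 other splits in all, in which between 6 and 15 lists passed. By list, the splits with a camera p as small as the real one numbered 1 for the integrated stress response, neural ectoderm and interferon lists, 2 for glycolysis, 3 for the germ line and 5 for the proteasome. They numbered 7 for the mesendoderm, formative and oxidative phosphorylation lists, 8 for the lysosome, 10 for 2-cell-like cells, 11 for the trophectoderm and 12 for DNA replication. Where only the real split gave so small a camera p, another split could come close. The unadjusted camera p was 1.71e-05 for the neural ectoderm list, against 9.62e-05 in the closest other split. For the interferon list it was 0.0057, against 0.013.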

How the results depend on the processing

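No named gene or list that passed the threshold, in any fit, had the opposite direction in another (for lists, camera's direction; the median of the microRNA list lay above 0 with median centring and without shGFP 5). Mkrn1 stayed past the threshold with every scaling, filter, eBayes setting, weight, block, probe set mean and left-out array, with a change between -0.64 and -0.57. It was not looked up for Welch's test, treat or the adjustment over every probe set. The number of called genes depended on the processing. Against 896, it was 1595 with only genes above the median level, where fewer genes were tested. It was 1548 for eBayes with a trend, 2757 with array weights and 1446 with a block of adjacent sample numbers. It was 378 adjusted over every probe set, where more tests were made, and 241 by Welch's test per gene (3529 at an unadjusted p under 0.05). For the trend, the weights, the block and Welch's test the cause was not tested. Of the 896, the trend kept 879, the weights 895 and the block 870. Genes changed at least 1.5-fold numbered 106, against 61 above the median level and 33 by treat, which tests against a 1.2-fold change. Lists past the threshold numbered 13, against 7 above the median level, 1 with an estimated correlation and 7 by fry, tests that allow for correlated members or ask another question. Quantile normalization (1096 genes), median centring (1000), robust eBayes (860) and the mean of probe sets (879) gave counts within 1.5 times of 896. So did leaving out arrays 7 and 8 (917), which was chosen after seeing the data. The share of called genes that were higher lay between 70.1% and 87.5%. Against 167 lower genes there were 290 with quantile normalization, 310 above the median level, 320 with a trend, 824 with array weights and 387 with the block, and without 1 array between 52 and 230.

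Without 1 array the counts lay between 309 and 852 for genes, 82 and 111 for genes past 1.5-fold, and 11 and 15 for lists. Fewer arrays widen the error, and the loss was greatest without shGFP 3 (324) or shMKRN1 6 (309). Of the 24 largest changes, 19 kept their call in all 8 of these fits. Of 52 other called genes named by the rule 17 did, and of 24 called genes chosen after their values were seen 12 did. In none of these did the change move over 1.5 times, while the medians of 7 of the 13 called lists did (formative, 2-cell-like, mesendoderm, oxidative phosphorylation, trophectoderm, neural, glycolysis). With only genes above the median level the germ line median was 0.59 and the neural median -0.08. Whether a named gene was called stayed the same in 1398 cases under the other alternatives, with 27 calls lost and 155 gained. Without 1 array it stayed the same in 1195 cases, with 232 calls lost and 12 gained. Cases that stayed the same include genes called in neither fit, so they do not give the share of calls that held. For the lists, counted likewise, the other alternatives left 198 the same, lost 11 calls and gained 6. Fits without 1 array left 219 the same, lost 7 and gained 6. Directions turned only where neither fit made a call: in 2 gene values and 9 list values under the other alternatives (Mkrn2 was at 0.01 with median centring), and in 1 and 24 without 1 array.

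Among lists with no called member, Welch's test passed 1 gene, in the DNA replication list. The block was tried because the sample numbers alternate. Deviations of arrays with adjacent numbers correlated at 0.13, -0.05, 0.26 and 0.64 across genes, against -0.53 to 0.41 for other array pairs, so the numbers were not taken to pair the samples. Lists were not run with robust eBayes or with the mean of probe sets, and the test of hairpin seed matches was not run at all. With 4 arrays per group most changes near 1.2-fold were missed in simulated data (20.9% recovered), and changes of dim probe sets are understated.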

Other observations

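The test on neighbouring genes and the gene families in this part were chosen after the values were seen, as were the genes named here that appear nowhere above. Some genes known from the germ line but outside the list fixed beforehand were also called; they were picked for their values and not tested as a group. The meiotic genes Rec114 (log2 change 0.78, SE 0.071; limma adjusted p = 0.000882), Hormad2 (0.66) and Stag3 (0.58) rose, as did Gtsf1 (6.28 in shGFP, 6.92 in shMKRN1) and Piwil4 (0.61), which act in transposon silencing by small RNAs, and the testis gene Tex15 (0.44). Tex11 was called higher at levels within the range of 95% of the silent receptor genes (5.79 in shGFP and 6.26 in shMKRN1, both below 6.53). The calls of Tex11 and Tex15 were lost without at least 1 array, and the 37 genes with the Tex stem did not pass as a family (median 0.01, adjusted p = 0.654). Among genes of DNA methylation, Dnmt1 (0.04, adjusted p = 0.716), Dnmt3b (0.06, adjusted p = 0.622) and Uhrf1 (0.05, adjusted p = 0.669) did not pass, while Dnmt3a rose by 0.25 (adjusted p = 0.0191) and the demethylase gene Tet1 fell by 0.23 (adjusted p = 0.0238). E2f6, which encodes a repressor of germ line genes, rose by 0.43 (SE 0.065; adjusted p = 0.00636). Besides Nlrp4c and Ccdc152, the genes among the 13 past 2-fold that the naming rule set aside for a low level were the retinoic acid hydroxylase gene Cyp26a1 (6.16 in shGFP, 7.43 in shMKRN1), Scml2 (6.44 and 7.55) and Ct55 (6.33 and 7.34). These 3 and Gtsf1 lay within the receptor range in shGFP, where changes are understated, so no size of change is given for them. Gpx4, a glutathione peroxidase gene that limits lipid peroxidation, rose by 0.80 (SE 0.086; adjusted p = 0.00154).

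Families of genes that share a symbol stem were tested with camera, and 5 of 326 passed at the preset correlation. With an estimated correlation 0 passed after adjustment (5 had an unadjusted p under 0.05). Late cornified envelope genes (Lce) were lower (median -0.14 over 19 genes, adjusted p = 0.000577, and 0.984 with an estimated correlation), but their median level of 5.63 is within the receptor range, so this is not read as a fall in expression of the family. Of them 4 were called: Lce1h, Lce1j (-0.35), Lce1g and Lce3c. Lce1g (3.57 in shGFP, 3.15 in shMKRN1) and Lce3c (5.94 and 5.59) lay within the receptor range in both groups, so their calls are not read as expression. Sprr1a, another cornified envelope gene, fell by 0.48. The calls of Lce1g, Lce1j, Lce3c and Sprr1a were lost without at least 1 array, and Lce3c kept its call in only 1 of the 8 fits. Mitochondrial ribosomal protein genes were higher, with a median of 0.11 over 48 genes of the large subunit (7 called, all higher) and 0.13 over 29 of the small subunit (3 called, all higher). Olfactory receptor (-0.04) and keratin-associated (-0.07) genes were slightly lower, also at median levels within the receptor range (4.64 and 5.89). The 5 directions were the same after quantile normalization and median centring, but sizes moved over 1.5 times. Quantile normalization gave medians of 0.07 and 0.08 for the mitochondrial subunits, and median centring gave -0.06 for the olfactory receptors. Splits of the arrays with a camera p as small numbered 2 of 35 for Lce, 4 and 1 for the subunits, 15 for the receptors and 13 for the keratin-associated genes. For the small subunit the unadjusted camera p was 1.22e-05, and another split gave 1.55e-05.

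Called genes lay next to each other on a chromosome more often than in random draws, though most called genes were in no such pair. Of 19855 genes with a position, 61 pairs of neighbours were called in the same direction, among them Dppa3 with Nanog, Nanog with Slc2a3, Dgat2 (0.32) with Mogat2, and Tsx (0.32) with Xist (0.61). The calls of Dgat2, Tsx and Xist were lost without at least 1 array. Pairs whose symbols share no stem numbered 56, against a mean of 24 in 10000 random draws. Draws matched on level gave a mean of 29.6 and at most 50 (permutation p = 1e-04, the smallest they can give). The stem compares symbols only, so related genes with different symbols may remain among these pairs. The draws shuffle genes, so their p does not measure the spread between arrays. Neighbouring genes may change together in these cells, through shared regulation or through transcription that runs from 1 gene into the next. Neither was tested, and the arrays do not separate them.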
